A study of Mus musculus with 8 samples.

How the data were processed

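The series holds RNA sequencing of liver from 8 mice, 4 given dexamethasone and 4 given saline. Per the labels, total RNA was depleted of ribosomal RNA and made into stranded libraries; reads were called with CASAVA 1.8 and aligned with TopHat2, and the processing notes name the human build hg19. Gene identifiers, symbols and positions in the table are those of mouse, and the tool used for counting is not stated. Of the 22565 gene identifiers, 21840 (96.79%) were found in the GENCODE M21 annotation of GRCm38, all on the same chromosome, 21826 on the same strand, and 19068 (84.50%) with a locus near the annotated ends or containing them.

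Per the file headers, 8 columns hold FPKM (fragments per kilobase of transcript, scaled to library size), one per library, computed by the authors with a denominator that is not stated. The other 8 columns, called counts in the header, were recorded here as a signal deposited by the authors: in each library 93.2% to 95.4% of values under 500 steps were whole multiples (tolerance 0.01 of a step) of one step that differed between libraries, so they were read as fragment counts scaled by one factor per library and not as raw counts. Dividing by the step gave the inferred fragments, and shares of fragments were taken from these columns. Only protein-coding genes are in the table, so the inferred fragments are not the full depth of a library.

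Gene tests used FPKM with R 4.3.3 and limma 3.58.1 (statmod 1.5.0): lmFit and eBayes with a mean-variance trend on log2(FPKM + 1), for genes at 0.5 FPKM or more in at least 4 libraries, with treatment as the only term. Tests were two-sided, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Replicate numbers are shared by the groups, but no label pairs the mice. Libraries were correlated on log2 values scaled between libraries, after the mean of each group was removed from each gene. By this measure 0 vehicle libraries were most alike to the dexamethasone library of their own number. Without removing the mean, each vehicle library correlated best with dexamethasone 1, vehicle 1 included. No pairing was used. Shares and sums were compared by two-sided exact permutation tests, adjusted over the 10 measures of the libraries and over the 13 sums of cell type markers.

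Gene lists, tests and the rule for named genes were chosen before the data were examined. The 48 lists covered glucocorticoid targets, glucose, amino acid, urea, lipid, cholesterol, lipoprotein, bile acid and drug metabolism, antioxidant genes, acute phase, inflammation, interferon response, the clock, the growth hormone axis, sex-biased genes, the cell cycle, p53, unfolded proteins, chaperones, the respiratory chain, hepatocyte identity and zonation, hepatokines, matrix, signs of RNA quality and markers of 13 other cell types. The 41 lists with at least 4 tested members were tested with camera (limma) with a preset inter-gene correlation of 0.01, against all other genes tested. Named genes were, first, the 12 of largest increase and the 12 of largest decrease among genes past the threshold with a mean of at least 1 FPKM in one group and groups that did not overlap, leaving out predicted genes. Second came the up to 4 members of smallest p of each list, and last 13 genes fixed whatever their values. Serpina3k, Serpina3m, Lars2, Cyp2b9, Cyp2b13 and members of gene families outside the lists were added after their values were seen.

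The steps were tested on simulated data with 200 of 10221 genes changed. The simulation was built from values scaled between libraries, so recovery with the deposited values was not measured. Of genes changed by 1 on the log2 scale 44% were recovered, and of those changed by 2 96% were. Changed genes were drawn from those at about 2 FPKM or more with vehicle, so recovery of lower genes was not measured. In these data 8 unchanged genes were called, the raised list was called and 0 other lists were. Values were shuffled gene by gene, so simulated genes were not correlated with each other. Real lists were (estimated inter-gene correlation 0.31 for glucocorticoid targets, 0.44 for cholesterol synthesis), so the simulation cannot show how often camera wrongly calls them. A shift of all genes by -0.28 alone gave 0 calls, and added to the changed genes it gave 54 higher and 135 lower calls against 77 and 71 without it.

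Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 1 FPKM, quantile normalization, median-ratio scaling (each library divided by its median ratio to the geometric mean library), robust empirical Bayes, array weights, no trend, replicate number as a term, a minimum log2 fold change of 1, each library left out in turn, and for lists an estimated correlation and fry. Added after seeing the data were the Lars2 share of summed FPKM, rescaling to fragments outside Lars2, zeros of abundant genes as missing, the scaled fragment counts in place of FPKM together with median-ratio scaling, and median-ratio scaling without dexamethasone 4, with replicate number as a term, or with an estimated correlation. A DESeq2 test, planned for counts, was not run because the values are not counts.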

Results

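Liver RNA was compared between male C57BL/6J mice that received dexamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, and mice that received saline as vehicle. The mice were 10 weeks old, and dexamethasone was given at 1.0 mg/kg by daily intraperitoneal injection for 14 days. Each group held 4 libraries, named here vehicle 1 to 4 and dexamethasone 1 to 4, and each library was RNA depleted of ribosomal RNA. The table listed 22565 protein-coding genes, of which 10221 reached 0.5 FPKM in at least 4 libraries and were tested. From the step of the scaled counts, the libraries held about 1361294 (dexamethasone 4) to 3360087 (vehicle 3) fragments on protein-coding genes, and 11977 to 13636 genes were above 0. This depth limits genes near the filter, where a few fragments set the value.

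Dexamethasone changed the liver transcriptome in both directions. Of genes known to be induced by the glucocorticoid receptor 12 of 22 rose, among them Fkbp5, Lcn2 and the metallothioneins Mt1 and Mt2, and so did Cyp2b10, a drug-metabolizing cytochrome P450. Of cholesterol synthesis genes 15 of 25 fell (14 also after median-ratio scaling), among them Insig1 and Sc4mol, as did Srebf1, which encodes a transcription factor of lipid synthesis, and 13 of 30 interferon response genes (6 also after scaling). In the values as deposited, 140 genes were higher and 802 lower with dexamethasone at an adjusted p under 0.05, so 85.1% of the calls were lower, and 2799 genes had an unadjusted p under 0.05. The median log2 fold change of all tested genes was -0.28, and after median-ratio scaling between libraries it was -0.02, with 325 genes higher and 337 lower (50.9% lower). Of these, 140 higher and 337 lower genes were called both ways, and 0 were called in opposite directions. Without vehicle 1, vehicle 2, vehicle 3 or dexamethasone 3 the number of lower genes as deposited was 382, 337, 380 and 448, and without dexamethasone 3 the number of higher genes was 81. Values below are from the deposited FPKM, so a gene with a log2 fold change of -0.28 moved with the median gene, and medians of lists are also given after scaling. In the deposited values the 4 libraries of each group did not overlap for 1882 of the tested genes (18.4%), against 2.86% expected by chance for 4 against 4. A shift shared by all genes also separates the groups, so this excess does not count regulated genes. Overlap after scaling was not counted.

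The share of scaled fragments on a single gene, Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was higher with dexamethasone. It was 21.8 ± 4.97% (SD, n = 4) with vehicle and 35.3 ± 10.7% (SD, n = 4) with dexamethasone, and each dexamethasone library (28.4% to 51.1%) lay above each vehicle library (14.5% to 25.3%; two-sided exact permutation p = 0.029, the smallest that 4 against 4 can give, 0.082 adjusted over 10 measures). Dexamethasone 4 had the highest share, and the difference between groups of 13.5 percentage points was 8.25 without it. Taken as a share of summed FPKM instead of scaled fragments, an alternative chosen after seeing the data, the difference over all 8 libraries was 7.02 percentage points. Whether these fragments came from Lars2 mRNA or from other RNA that aligned there was not tested. Lars2 FPKM did not pass the test (log2 fold change 0.54 ± 0.25, adjusted p = 0.19). Fewer genes were detected with dexamethasone (12641 ± 469 against 13316 ± 236, SD, n = 4, exact permutation p = 0.029, adjusted 0.082). Inferred fragments outside Lars2 numbered 665936 to 1581776 in the dexamethasone libraries and 1636129 to 2571864 in the vehicle libraries, so each dexamethasone library also had less depth for other genes. The share on albumin was 4.68 ± 1.4% against 6.31 ± 1.03% with vehicle (SD, n = 4, exact permutation p = 0.057, adjusted 0.082), and the share on mitochondrially encoded genes was 3.91 ± 0.659% against 3.87 ± 1.03% (SD, n = 4, exact permutation p = 0.94, adjusted 0.94). Both shares count Lars2 in their total, so a larger Lars2 share lowers them. Outside Lars2 the mitochondrial share was 6.30 ± 2.15% with dexamethasone and 5.03 ± 1.56% with vehicle (SD, n = 4, exact permutation p = 0.43, adjusted 0.48). The albumin share outside Lars2 was not taken.

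**Figure D1:**
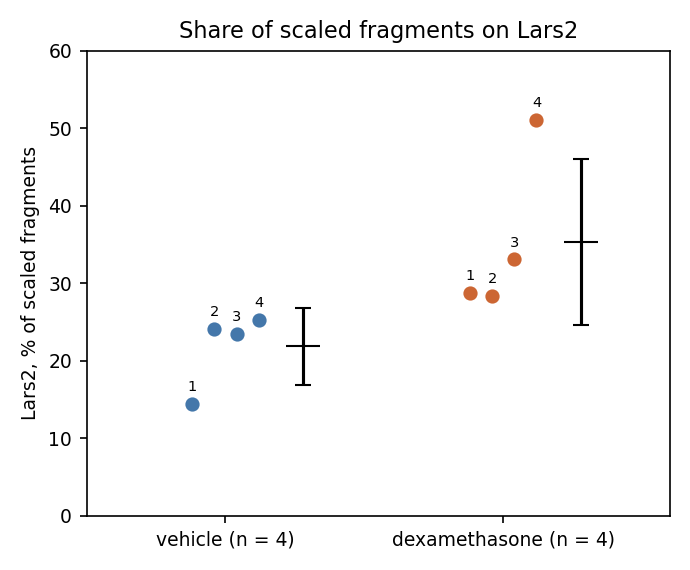
Percent of the scaled fragments of each library that lay on Lars2, by group; points are libraries with their replicate numbers, and bars are the mean and SD of 4 libraries. The dexamethasone libraries lie between 28.4% and 51.1%, above the vehicle libraries at 14.5% to 25.3%.

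The 12 genes of largest increase among those whose groups did not overlap were Cyp2b10, Lcn2, Mt2, Mt1, Fam107a, Ppp1r3c, Gadd45b, Sult1e1, Cyp4a14, Cdkn1a, Ddit4 and Saa1, and all passed before and after median-ratio scaling. Cyp2b10 (ENSMUSG00000030483, chromosome 7, 25897620 to 25926624, plus strand in the GRCm38 mouse genome, as are the positions below) went from 0.475 ± 0.14 to 219 ± 38.2 FPKM (SD, n = 4), a log2 fold change of 7.21 ± 0.20, adjusted p = 1.8e-10. Log2 fold changes, here and below with their SE, were taken on log2(FPKM + 1), which understates the change of low genes. Lcn2, which encodes an iron-siderophore-binding acute phase protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, minus strand), went from 2.36 ± 1.66 to 151 ± 47.6 FPKM (5.58 ± 0.35, adjusted p = 6.3e-07). The metal-binding metallothioneins Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568, plus strand) and Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327, plus strand) lie next to each other, and both rose. Mt2 went from 1.25 ± 0.637 to 101 ± 41.3 FPKM (5.43 ± 0.32, adjusted p = 5.3e-07) and Mt1 from 5.54 ± 2.5 to 197 ± 72.9 FPKM (4.93 ± 0.36, adjusted p = 3.3e-06). Ppp1r3c, a regulatory subunit of the phosphatase that activates glycogen synthase (ENSMUSG00000067279, chromosome 19, 36731731 to 36736653, minus strand), rose from 1.52 ± 0.261 to 41.7 ± 10.9 FPKM (4.05 ± 0.23, adjusted p = 4.7e-07). Gadd45b, a stress-induced gene (4.02 ± 0.22, adjusted p = 3.1e-07), Ddit4, an inhibitor of mTORC1 signalling (3.26 ± 0.27, adjusted p = 1.5e-05), and Saa1, an acute phase apolipoprotein (3.12 ± 0.38, adjusted p = 5.4e-04), rose as well. Cyp4a14, a fatty acid hydroxylase, went from 18.3 ± 26.9 to 131 ± 72.1 FPKM (3.62 ± 0.72, adjusted p = 0.0091), with 58.5 FPKM in vehicle 1 and at most 7.08 FPKM in the other vehicle libraries. For 3 of these genes some vehicle libraries were listed at 0. Fam107a had 0, 0.161, 0.0543 and 0.164 FPKM in the vehicle libraries and 21.7, 17.5, 15.9 and 24 FPKM in the dexamethasone libraries. Sult1e1, the oestrogen sulfotransferase, had 0.371, 0, 0 and 0.135 FPKM in the vehicle libraries and 23.3, 13.8, 17.8 and 11.8 FPKM in the dexamethasone libraries. Cdkn1a, which encodes the cell cycle inhibitor p21, had 0, 0, 0.147 and 0 FPKM in the vehicle libraries and 10.6, 8.83, 12.4 and 9.88 FPKM in the dexamethasone libraries.

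The 12 genes of largest decrease were Aox3, Ugt2b38, Apol7a, Serpina6, Mup17, Slc22a30, Insig1, Srebf1, Cyp2a5, Sucnr1, Sc4mol and Ghr, again passing before and after scaling. Aox3, an aldehyde oxidase (ENSMUSG00000064294, chromosome 1, 58113130 to 58200698, plus strand), went from 97.9 ± 26.6 to 16.8 ± 9.9 FPKM (SD, n = 4; -2.58 ± 0.32, adjusted p = 6.0e-04). Serpina6, which encodes the corticosteroid-binding globulin of plasma (ENSMUSG00000060807, chromosome 12, 103646630 to 103657212, minus strand), went from 65 ± 17.9 to 11.6 ± 4.72 FPKM (-2.46 ± 0.31, adjusted p = 6.0e-04). Ghr, the growth hormone receptor (ENSMUSG00000055737, chromosome 15, 3317760 to 3583492, minus strand), went from 101 ± 13.5 to 24.6 ± 9.43 FPKM (-2.08 ± 0.28, adjusted p = 9.1e-04). Insig1, a sterol-regulated inhibitor of SREBP processing (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662, plus strand), went from 31.3 ± 4.33 to 6.33 ± 2.27 FPKM (-2.19 ± 0.25, adjusted p = 3.6e-04), and Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581, minus strand) from 81.3 ± 31 to 16.4 ± 2.27 FPKM (-2.19 ± 0.24, adjusted p = 2.8e-04). Sc4mol, the older symbol of the sterol methyl oxidase Msmo1 (ENSMUSG00000031604, chromosome 8, 64718139 to 64733792, minus strand), went from 42.7 ± 7.68 to 9.95 ± 5.31 FPKM (-2.13 ± 0.33, adjusted p = 0.0020). Ugt2b38 (-2.55 ± 0.37, adjusted p = 0.0013), a glucuronosyltransferase, Cyp2a5 (-2.18 ± 0.31, adjusted p = 0.0011), Apol7a (-2.51 ± 0.28, adjusted p = 2.8e-04), the transporter gene Slc22a30 (-2.23 ± 0.26, adjusted p = 4.1e-04) and the succinate receptor gene Sucnr1 (-2.14 ± 0.36, adjusted p = 0.0033) fell too. Mup17 (-2.42 ± 0.42, adjusted p = 0.0045) belongs to the major urinary protein genes, 5 of which (Mup1, Mup8, Mup9, Mup10 and Mup11) were listed at 0 in 6 of the 8 libraries, so values of this family are uncertain.

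**Figure D2:**
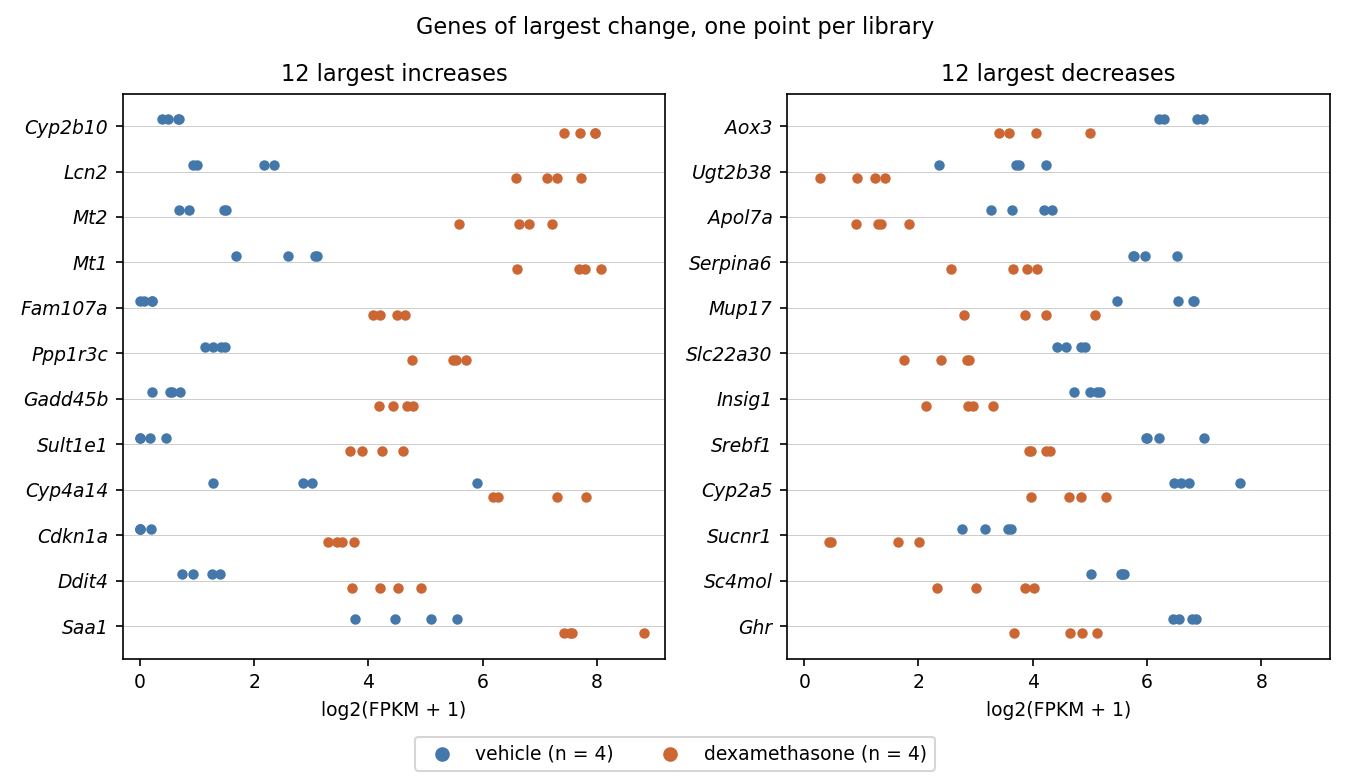
Values on a log2(FPKM + 1) axis of the 12 genes with the largest increase (left) and the 12 with the largest decrease (right), each point a library, with 4 vehicle and 4 dexamethasone libraries a gene. In each of the 24 genes the groups do not overlap, and Cyp2b10 has the largest log2 fold change, 7.21.

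Genes widely induced by the glucocorticoid receptor moved up as a group. Of this list, 12 of the 22 tested members rose and 0 fell (camera adjusted p = 1.9e-35, scaled 3.8e-26), a call lost with an inter-gene correlation estimated from the data (adjusted p = 0.090 with an estimated correlation, and 0.039 after scaling). After scaling 14 and 0 passed, and 12 and 0 did adjusted over the list alone. Its median log2 fold change was 1.29 (1.65 after scaling). Its members of smallest p were Gadd45b, Cdkn1a, Mt2 and Sult1e1, given above. Fkbp5, a cochaperone of the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527, minus strand), rose from 6.87 ± 1.2 to 59.7 ± 8.73 FPKM (SD, n = 4; 2.95 ± 0.21, adjusted p = 2.4e-06). Tat, another member fixed for report, rose and is given with amino acid breakdown. Tsc22d3 (0.54 ± 0.35, adjusted p = 0.34), the clock gene Per1 (0.07 ± 0.29, adjusted p = 0.90) and Klf9 (0.23 ± 0.23, adjusted p = 0.54), fixed likewise, did not pass. The receptor gene itself, Nr3c1, had 9.87 ± 1.53 FPKM with vehicle and 4.81 ± 1.25 FPKM with dexamethasone (SD, n = 4), a decrease that passed as deposited but not after scaling (-0.92 ± 0.22, adjusted p = 0.021, 0.087 after scaling). Hsd11b1, whose product regenerates active glucocorticoid, did not pass (-0.55 ± 0.27, adjusted p = 0.21).

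Among genes of glucose metabolism, few gluconeogenic enzymes passed singly. For gluconeogenesis, 1 of the 21 tested members rose and 1 fell, and camera placed the list above other genes (camera adjusted p = 0.0042, scaled 4.9e-05, adjusted p = 0.93 with an estimated correlation) although its median as deposited was -0.02 and its mean 0.04 (median 0.36 after scaling). Adjusted over the list alone 1 rose and 1 fell, and after scaling 4 and 0 did. Pcx, pyruvate carboxylase, rose from 24.6 ± 1.9 to 43.3 ± 3.5 FPKM (0.79 ± 0.18, adjusted p = 0.017), whereas the mitochondrial pyruvate carrier subunit gene Mpc2 was lower only as deposited (-0.93 ± 0.27, adjusted p = 0.045, 0.21 after scaling), and Ppargc1a (0.77 ± 0.25, adjusted p = 0.065) and Hnf4a (0.52 ± 0.18, adjusted p = 0.090, 0.012 after scaling) did not pass as deposited. Pck1, which catalyses the committed step of gluconeogenesis, had 483 ± 106 FPKM with vehicle and 436 ± 54.4 FPKM with dexamethasone (SD, n = 4) and did not pass (-0.12 ± 0.21, adjusted p = 0.74, 0.33 after scaling). Neither did G6pc, the catalytic subunit of glucose-6-phosphatase (-0.30 ± 0.42, adjusted p = 0.67, 0.92 after scaling). The signs of both flipped with scaling, to 0.27 and 0.09. In glycolysis and glycogen metabolism, 1 of the 23 tested members rose and 4 fell (camera adjusted p = 0.12, scaled 0.078). Scaled values gave 3 higher and 1 lower, against 1 and 5 adjusted over the list alone. Besides Ppp1r3c, Ugp2 fell (-1.23 ± 0.30, adjusted p = 0.023), and Ppp1r3g (-0.87 ± 0.23, adjusted p = 0.032, 0.11 after scaling) and the liver glycogen synthase gene Gys2 (-0.89 ± 0.25, adjusted p = 0.043, 0.22 after scaling) were lower only as deposited. In the insulin pathway, 1 of the 22 tested members rose and 1 fell (camera adjusted p = 0.54, scaled 0.24), with Igfbp1, an insulin-repressed gene, rising from 19.6 ± 9.8 to 49.6 ± 10.6 FPKM (1.38 ± 0.30, adjusted p = 0.012), Igfbp2 lower only as deposited (-0.75 ± 0.21, adjusted p = 0.043, 0.32 after scaling), and Grb14 and Tsc1 not passing (adjusted p from 0.19 to 0.21). The counts were 2 and 0 after scaling and 1 and 1 adjusted over the list alone.

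Genes of amino acid breakdown were higher relative to other genes. For this list, 4 of the 36 tested members rose and 1 fell (camera adjusted p = 0.0042, scaled 1.8e-05, adjusted p = 0.93 with an estimated correlation), with a median of -0.07 as deposited, opposite in sign to the test and to its mean of 0.02, and 0.31 after scaling. With scaling they numbered 11 and 0, and adjusted over the list alone 5 and 3. Tat, tyrosine aminotransferase, a classical glucocorticoid-induced enzyme, rose from 179 ± 71.6 to 442 ± 80.8 FPKM (SD, n = 4; 1.39 ± 0.30, adjusted p = 0.013). Tdo2, which opens tryptophan breakdown, rose from 153 ± 17.6 to 278 ± 58.4 FPKM (0.84 ± 0.21, adjusted p = 0.026), as did the glycine decarboxylase gene Gldc (1.13 ± 0.19, adjusted p = 0.0037) and Bhmt, which remethylates homocysteine (1.04 ± 0.26, adjusted p = 0.025). In the urea cycle, 0 of the 10 tested members rose and 1 fell (camera adjusted p = 0.16, scaled 0.011, scaled adjusted p = 0.42 with an estimated correlation). Scaling gave 3 and 1, and 0 and 1 passed adjusted over the list alone. Otc, ornithine transcarbamylase, fell from 41.6 ± 3.97 to 18.1 ± 7.28 FPKM (-1.25 ± 0.28, adjusted p = 0.016), Cps1 (0.31 ± 0.21, adjusted p = 0.35, 0.0066 after scaling) and Arg1 (0.24 ± 0.19, adjusted p = 0.43, 0.014 after scaling) were higher only after scaling, and Glud1 did not pass (-0.25 ± 0.22, adjusted p = 0.48).

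Cholesterol synthesis genes were lower as a group. Of this list, 0 of the 25 tested members rose and 15 fell (camera adjusted p = 8.8e-11, scaled 5.8e-13), with a median log2 fold change of -1.27 (-0.90 after scaling); the call was lost with an estimated correlation (adjusted p = 0.72 with an estimated correlation). These numbers were 0 and 20 adjusted over the list alone, and 0 and 14 scaled. Besides Insig1, the sterol transport gene Stard4 fell from 8.13 ± 1.35 to 1.57 ± 0.492 FPKM (-1.84 ± 0.22, adjusted p = 4.8e-04), and Sc5d, a desaturase of the last steps of the pathway, from 75.7 ± 15.7 to 19.5 ± 6.64 FPKM (-1.94 ± 0.27, adjusted p = 0.0010). In lipogenesis, 3 of the 25 tested members rose and 8 fell (camera adjusted p = 0.38, scaled 0.24), and members went both ways. After scaling 4 and 4 passed, and 3 and 11 did adjusted over the list alone. Srebf1 and the fatty acid desaturase gene Fads2 (-1.25 ± 0.25, adjusted p = 0.0093) fell, Lpin1, a phosphatidate phosphatase, rose from 16 ± 6.29 to 67.8 ± 23.9 FPKM (2.05 ± 0.33, adjusted p = 0.0027), and Acacb, whose product makes the malonyl-CoA that restrains mitochondrial fatty acid uptake, rose (1.29 ± 0.25, adjusted p = 0.0077). Fasn, fatty acid synthase, had 29.7 ± 17.4 FPKM with vehicle and 9.17 ± 1.11 FPKM with dexamethasone (SD, n = 4) and was lower only as deposited (-1.41 ± 0.34, adjusted p = 0.023, 0.093 after scaling). In lipid storage, 3 of the 22 tested members rose and 1 fell (camera adjusted p = 0.078, scaled 0.078). Adjusted over the list alone 4 rose and 3 fell, and after scaling 4 and 1 did. The lipid droplet proteins Plin5 (5.7 ± 1.29 to 32 ± 4.31 FPKM; 2.31 ± 0.21, adjusted p = 3.2e-05), Plin4 (1.42 ± 0.23, adjusted p = 0.0023) and Plin3 (0.94 ± 0.23, adjusted p = 0.024) rose, and Fabp1, the liver fatty acid binding protein, fell (-1.0 ± 0.22, adjusted p = 0.014). In fatty acid oxidation, 2 of the 33 tested members rose and 3 fell (camera adjusted p = 0.13, scaled 0.035, scaled adjusted p = 0.56 with an estimated correlation). Scaled values gave 5 higher and 2 lower, against 4 and 5 adjusted over the list alone. The peroxisomal enzyme gene Acaa1b (118 ± 14.8 to 32.2 ± 4.31 FPKM; -1.84 ± 0.19, adjusted p = 1.4e-04) fell, whereas the peroxisome proliferation gene Pex11a (0.94 ± 0.21, adjusted p = 0.017) and Cyp4a14 rose.

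In the lipoprotein list, 2 of the 27 tested members rose and 3 fell (camera adjusted p = 0.73, scaled 0.22). The counts were 2 and 2 after scaling and 2 and 3 adjusted over the list alone. Apoa4, an apolipoprotein, rose from 11 ± 2.98 to 89 ± 13.7 FPKM (SD, n = 4; 2.93 ± 0.23, adjusted p = 6.9e-06), and Angptl4, a lipoprotein lipase inhibitor, from 29 ± 9.21 to 66.2 ± 13.1 FPKM (1.19 ± 0.24, adjusted p = 0.0089). Abcg5, a subunit of the sterol exporter into bile, fell from 27.7 ± 5.25 to 7.22 ± 1.85 FPKM (-1.81 ± 0.23, adjusted p = 6.0e-04), and Sort1 fell (-1.39 ± 0.19, adjusted p = 0.0010). In bile acid synthesis and transport, 1 of the 26 tested members rose and 7 fell (camera adjusted p = 0.084, scaled 0.14). With scaling they numbered 2 and 4, and adjusted over the list alone 1 and 9. Cyp39a1, an oxysterol hydroxylase, rose (1.75 ± 0.28, adjusted p = 0.0026), and the transporters Abcc3 (-1.26 ± 0.21, adjusted p = 0.0027), Abcc2 (-1.15 ± 0.20, adjusted p = 0.0046) and Slco1a1 (-1.27 ± 0.28, adjusted p = 0.014) fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 48.6 ± 16.2 FPKM with vehicle and 21.5 ± 18.4 FPKM with dexamethasone (SD, n = 4) and did not pass (-1.37 ± 0.42, adjusted p = 0.059). In drug metabolism, 4 of the 39 tested members rose and 10 fell (camera adjusted p = 0.68, scaled 0.84). Scaling gave 6 and 8, and 5 and 18 passed adjusted over the list alone. Against the rise of Cyp2b10, Cyp2c54 fell from 83.1 ± 24.4 to 20.2 ± 7.01 FPKM (-2.02 ± 0.28, adjusted p = 9.9e-04), and Nr1i3, which encodes the nuclear receptor CAR, fell from 109 ± 27 to 31 ± 6.35 FPKM (-1.78 ± 0.22, adjusted p = 6.0e-04). In the antioxidant list, 0 of the 19 tested members rose and 2 fell (camera adjusted p = 0.38, scaled 0.55). These numbers were 0 and 2 adjusted over the list alone, and 0 and 1 scaled. Nfe2l2, the gene of the transcription factor NRF2, fell (-1.43 ± 0.28, adjusted p = 0.0079), Gclm was lower only as deposited (-1.26 ± 0.33, adjusted p = 0.033, 0.075 after scaling), and Prdx1 and Sod2 did not pass (adjusted p from 0.085 to 0.11).

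Acute phase genes went in both directions. Of the list, 9 of the 34 tested members rose and 4 fell (camera adjusted p = 0.012, scaled 0.027, adjusted p = 0.93 with an estimated correlation). After scaling 10 and 3 passed, and 9 and 9 did adjusted over the list alone. The median was -0.30 and the mean -0.20 as deposited, against the direction of the test, and 0.08 after scaling. Saa4 rose from 27.9 ± 2.28 to 135 ± 23.8 FPKM (SD, n = 4; 2.23 ± 0.19, adjusted p = 2.2e-05), along with Lcn2 and Saa1, and Fgl1, a fibrinogen-like protein, fell from 75.8 ± 10.2 to 21.5 ± 10.3 FPKM (-1.92 ± 0.34, adjusted p = 0.0046). The members counted as lower include Serpina3k, which was listed at 0 in dexamethasone 1, 2 and 3 and at 4080 FPKM in dexamethasone 4, against 2303 to 3353 FPKM in the vehicle libraries. This call was lost after scaling and is uncertain. In the interferon response and antigen presentation, 0 of the 30 tested members rose and 13 fell (camera adjusted p = 4.0e-04, scaled 5.0e-05, adjusted p = 0.72 with an estimated correlation), with a median of -0.70 (-0.44 after scaling). Adjusted over the list alone 0 rose and 16 fell, and after scaling 0 and 6 did. The interferon-inducible GTPase genes Iigp1 (18.1 ± 2.65 to 4.12 ± 1.54 FPKM; -1.95 ± 0.26, adjusted p = 9.0e-04), Igtp (-1.54 ± 0.21, adjusted p = 0.0010) and Irgm2 (-1.40 ± 0.20, adjusted p = 0.0010) fell, and so did the MHC class II gene H2-Aa (-1.59 ± 0.23, adjusted p = 0.0014). Beside this list, 3 of the sums of immune cell markers had unadjusted p of 0.029, and none of the sums passed after adjustment. Summed FPKM of dendritic cell markers was 44.3 ± 9.71 with vehicle and 25.3 ± 8.03 with dexamethasone (SD, n = 4, exact permutation p = 0.029, 0.12 adjusted over 13 sums, and an unadjusted 0.14 after scaling). Of the dendritic cell sum, Bst2, an interferon-induced gene that the interferon list also holds, had 38.9 FPKM with vehicle and 20.8 FPKM with dexamethasone and carried most of the difference. The sums of T cell markers were 4.01 ± 1.69 and 1.14 ± 0.201, and of neutrophil markers 1.62 ± 0.367 and 0.409 ± 0.194 (SD, n = 4, exact permutation p = 0.029 for each, adjusted 0.12). Kupffer cell markers summed to 172 ± 17.8 and 172 ± 36.3 (SD, n = 4, exact permutation p = 1), and those of B cells, NK cells and monocytes had exact permutation p of 0.14, 0.69 and 0.11. The myeloid gene Lyz2 fell (-1.44 ± 0.28, adjusted p = 0.0075). Of the inflammation list, 0 of the 10 tested members rose and 3 fell (camera adjusted p = 0.21, scaled 0.15). Scaled values gave 1 higher and 1 lower, against 0 and 5 adjusted over the list alone. Il18 had 1.96, 1.75, 3.8 and 1.77 FPKM in the vehicle libraries and 0, 0.393, 0 and 0 FPKM in the dexamethasone libraries (adjusted p = 0.0013), Irf1 (-1.30 ± 0.28, adjusted p = 0.013, 0.051 after scaling) and Cxcl16 (-0.91 ± 0.24, adjusted p = 0.033, 0.093 after scaling) were lower only as deposited, and Bcl3 did not pass (-0.73 ± 0.25, adjusted p = 0.085).

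In the list of clock genes, 2 of the 18 tested members rose and 5 fell (camera adjusted p = 0.86, scaled 0.86). The counts were 4 and 2 after scaling and 2 and 6 adjusted over the list alone. Per3 (-1.42 ± 0.21, adjusted p = 0.0014) and the clock output gene Dbp (-1.50 ± 0.23, adjusted p = 0.0020) fell, Nfil3, a repressor of the same promoter elements that Dbp activates, rose (1.34 ± 0.24, adjusted p = 0.0052), and Tef was lower only as deposited (-0.91 ± 0.18, adjusted p = 0.0080, 0.068 after scaling). In the growth hormone axis, 1 of the 15 tested members rose and 3 fell (camera adjusted p = 0.38, scaled 0.32). With scaling they numbered 1 and 2, and adjusted over the list alone 1 and 7. Besides Ghr, the prolactin receptor gene Prlr fell from 14.9 ± 8.29 to 2.73 ± 1.45 FPKM (SD, n = 4; -2.06 ± 0.36, adjusted p = 0.0046). Igf1, the main growth hormone effector made by liver, had 95.7 ± 18.2 FPKM with vehicle and 70.5 ± 23 FPKM with dexamethasone (SD, n = 4) and did not pass (-0.49 ± 0.27, adjusted p = 0.26). Of genes higher in male than female mouse liver, 1 of the 23 tested members rose and 8 fell (camera adjusted p = 0.59, scaled 0.41), with Cyp2u1 (-1.85 ± 0.22, adjusted p = 4.1e-04), Nudt7 (-1.92 ± 0.27, adjusted p = 0.0011) and Keg1 (-1.62 ± 0.28, adjusted p = 0.0042) falling beside Ugt2b38. Scaling gave 1 and 6, and 1 and 10 passed adjusted over the list alone. Of genes higher in female liver, 1 of the 6 tested members rose and 1 fell (camera adjusted p = 0.016, scaled 0.078, adjusted p = 0.72 with an estimated correlation). These numbers were 2 and 2 adjusted over the list alone, and 2 and 1 scaled. Only Sult1e1 rose as deposited, a gene the glucocorticoid list also holds, and Lifr fell (-1.15 ± 0.22, adjusted p = 0.0075), while Fmo2 was higher only after scaling (0.84 ± 0.26, adjusted p = 0.061, 0.0095 after scaling). Cyp2c40, listed at 0 in dexamethasone 4, did not pass (adjusted p = 0.072).

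For stress programmes, 2 of the 12 tested members rose and 0 fell in the p53 target list (camera adjusted p = 0.0064, scaled 0.052, adjusted p = 0.72 with an estimated correlation), whose median as deposited was -0.23, below 0 although its mean was 0.37 and camera placed the list higher. After scaling 2 and 0 passed, and 2 and 2 did adjusted over the list alone. Its 2 risen members were Cdkn1a, which the glucocorticoid list also holds, and Gdf15, a stress-induced cytokine, from 0.459 ± 0.228 to 6.7 ± 2.02 FPKM (SD, n = 4; 2.38 ± 0.24, adjusted p = 1.2e-04). Mdm2 and Ccng1 did not pass (adjusted p from 0.066 to 0.083). In the unfolded protein list, 1 of the 27 tested members rose and 2 fell (camera adjusted p = 0.38, scaled 0.17). Adjusted over the list alone 1 rose and 2 fell, and after scaling 4 and 0 did. Ddit3 rose (0.99 ± 0.28, adjusted p = 0.045), Xbp1 (-0.80 ± 0.23, adjusted p = 0.046, 0.22 after scaling) and Pdia3 (-0.89 ± 0.25, adjusted p = 0.047, 0.14 after scaling) were lower only as deposited, and Canx did not pass (-0.56 ± 0.19, adjusted p = 0.076). Among cytosolic chaperones, 0 of the 15 tested members rose and 0 fell (camera adjusted p = 0.65, scaled 0.88). Scaled values gave 0 higher and 0 lower, against 0 and 0 adjusted over the list alone. Hsp90aa1, Fkbp4, Dnaja1 and Ahsa1 had the smallest p (adjusted p from 0.083 to 0.23). Of cell cycle genes, 0 of the 7 tested members rose and 2 fell (camera adjusted p = 0.73, scaled 0.45). The counts were 0 and 0 after scaling and 0 and 3 adjusted over the list alone. Tk1 (-1.05 ± 0.22, adjusted p = 0.012, 0.13 after scaling) and Ccnd1 (-0.79 ± 0.22, adjusted p = 0.038, 0.094 after scaling) were lower only as deposited, and Tyms and Pcna did not pass (adjusted p from 0.066 to 0.16). Of immediate early genes, 1 of the 7 tested members rose and 0 fell (camera adjusted p = 0.16, scaled 0.20), with Jun rising (0.86 ± 0.24, adjusted p = 0.038) and Junb, Maff and Btg2 not passing (adjusted p from 0.27 to 0.48). With scaling they numbered 1 and 0, and adjusted over the list alone 1 and 0.

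For hepatocyte identity, 0 of the 18 tested members rose and 2 fell (camera adjusted p = 0.084, scaled 0.17). Scaling gave 1 and 2, and 1 and 4 passed adjusted over the list alone. The transcription factor genes Foxa1 (-1.09 ± 0.21, adjusted p = 0.0067) and Onecut2 (-1.06 ± 0.24, adjusted p = 0.016) fell, and Ambp and Cebpa did not pass (adjusted p from 0.071 to 0.078). Of pericentral genes, 0 of the 16 tested members rose and 4 fell (camera adjusted p = 0.38, scaled 0.52). These numbers were 0 and 5 adjusted over the list alone, and 1 and 2 scaled. Rgn (-1.51 ± 0.27, adjusted p = 0.0048) and the Wnt target Lgr5 (-1.34 ± 0.28, adjusted p = 0.010) fell, and Rnf43 (-1.32 ± 0.32, adjusted p = 0.023, 0.16 after scaling) and Oat (-1.02 ± 0.28, adjusted p = 0.041, 0.12 after scaling) were lower only as deposited. Of periportal genes, 0 of the 13 tested members rose and 1 fell (camera adjusted p = 0.76, scaled 0.29), with Ctsc falling (-1.14 ± 0.26, adjusted p = 0.018) and Pigr, Hsd17b13 and Cyp2f2 not passing (adjusted p from 0.079 to 0.10). After scaling 2 and 1 passed, and 0 and 1 did adjusted over the list alone. Of secreted hepatokines, 2 of the 18 tested members rose and 1 fell (camera adjusted p = 0.55, scaled 0.45), namely Gdf15 and Angptl4 upward, Lect2 lower only as deposited (-1.11 ± 0.27, adjusted p = 0.024, 0.073 after scaling) and Hgf not passing (-0.68 ± 0.23, adjusted p = 0.077). Adjusted over the list alone 2 rose and 2 fell, and after scaling 2 and 0 did. In the matrix list, 1 of the 24 tested members rose and 0 fell (camera adjusted p = 0.057, scaled 0.052). Scaled values gave 2 higher and 0 lower, against 0 and 0 adjusted over the list alone. Ctgf rose (1.35 ± 0.37, adjusted p = 0.038), Col4a2 was higher only after scaling (0.39 ± 0.19, adjusted p = 0.21, 0.026 after scaling), and Col14a1 and Col5a2 did not pass (adjusted p from 0.15 to 0.29).

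**Figure D3:**
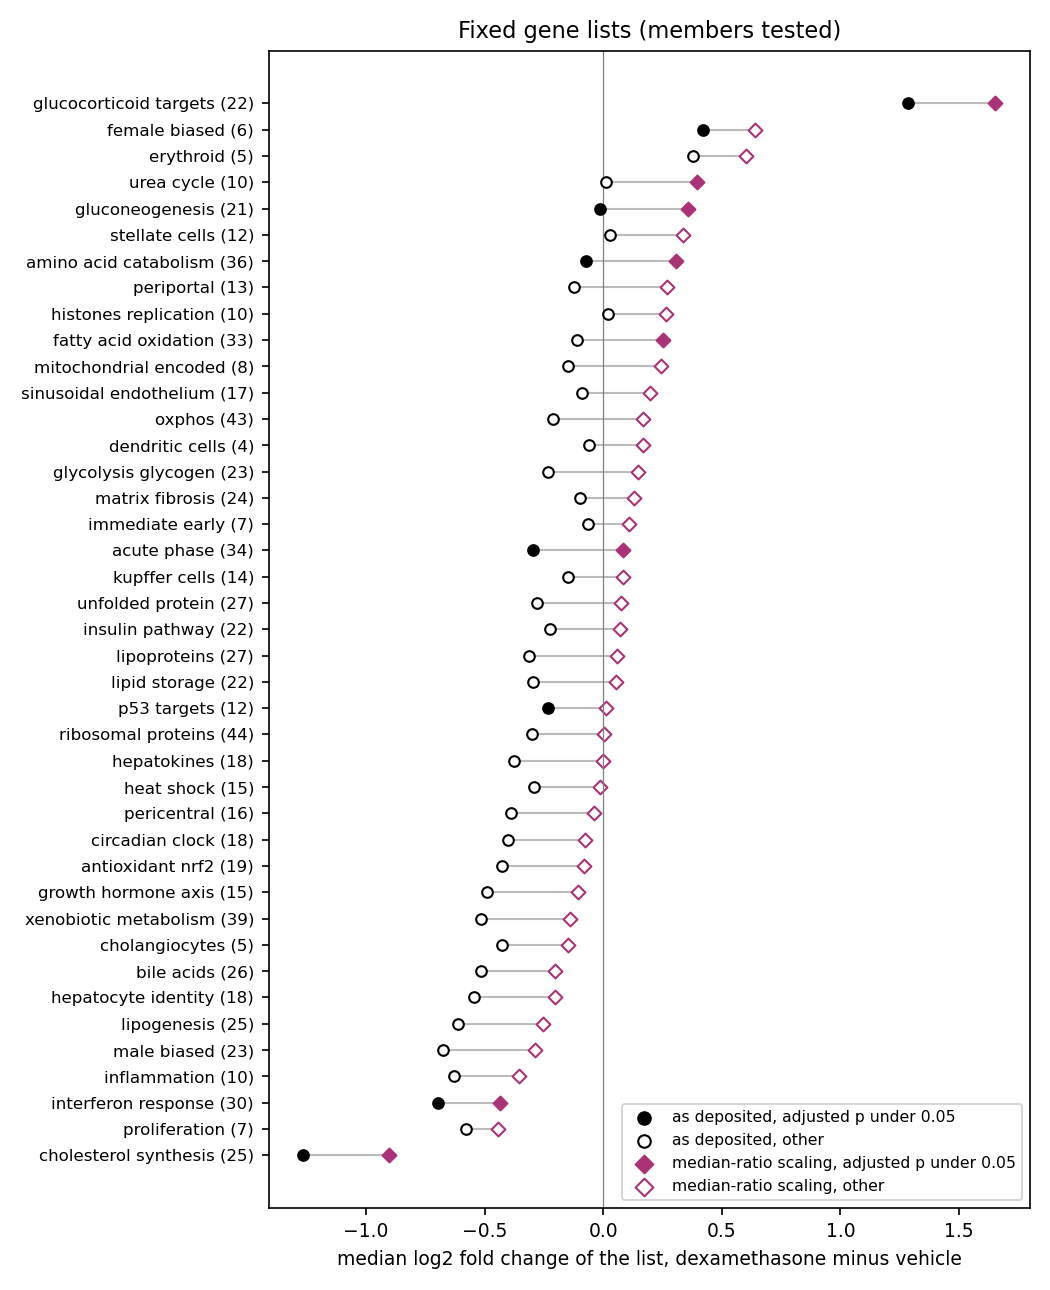
Median log2 fold change, dexamethasone minus vehicle, of each fixed list with at least 4 tested members (their number in brackets), as deposited (circles) and after median-ratio scaling (diamonds), filled where the camera adjusted p is under 0.05. Glucocorticoid targets lie highest at 1.29 as deposited, and cholesterol synthesis lowest at -1.27, and all 41 medians are higher after scaling.

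Markers of cells other than hepatocytes were listed because bulk liver holds them. For Kupffer cells, 0 of the 14 tested members rose and 0 fell (camera adjusted p = 0.44, scaled 0.38). The counts were 0 and 0 after scaling and 0 and 0 adjusted over the list alone. Cd5l, Emr1, Cd163 and Cd68 had the smallest p (adjusted p from 0.054 to 0.27). For sinusoidal endothelium, 1 of the 17 tested members rose and 1 fell (camera adjusted p = 0.17, scaled 0.059). With scaling they numbered 4 and 0, and adjusted over the list alone 1 and 1. Lyve1 rose (1.05 ± 0.28, adjusted p = 0.034), Kdr was lower only as deposited (-0.80 ± 0.19, adjusted p = 0.022, 0.13 after scaling), Oit3 was higher only after scaling (0.67 ± 0.25, adjusted p = 0.10, 0.015 after scaling) and Fcgr2b did not pass (-0.53 ± 0.18, adjusted p = 0.090). For stellate cells, 0 of the 12 tested members rose and 1 fell (camera adjusted p = 0.16, scaled 0.078). Scaling gave 0 and 1, and 0 and 1 passed adjusted over the list alone. Cxcl12 fell from 53.4 ± 8.89 to 21.6 ± 6.12 FPKM (SD, n = 4; -1.29 ± 0.23, adjusted p = 0.0045), and Hgf, Pdgfra and Hand2 did not pass (adjusted p from 0.077 to 0.37). For dendritic cells, 0 of the 4 tested members rose and 0 fell (camera adjusted p = 0.77, scaled 0.88). These numbers were 0 and 1 adjusted over the list alone, and 0 and 0 scaled. Of its members, Bst2, Zbtb46, Irf8 and Clec9a did not pass (adjusted p from 0.055 to 0.99). For cholangiocytes, 0 of the 5 tested members rose and 0 fell (camera adjusted p = 0.55, scaled 0.35). After scaling 0 and 0 passed, and 0 and 1 did adjusted over the list alone. Of its members, Spp1, Epcam and Pkhd1 did not pass (adjusted p from 0.23 to 0.42). For red cells, 0 of the 5 tested members rose and 0 fell (camera adjusted p = 0.084, scaled 0.10). Adjusted over the list alone 0 rose and 0 fell, and after scaling 0 and 0 did. Of its members, Hbb-bs, Hba-a2, Alas2 and Hbb-bt did not pass (adjusted p from 0.18 to 0.43). Lists of T cells, B cells, NK cells, monocytes, neutrophils, adipocytes and acinar cells had fewer than 4 tested members and no list test. Of those members, Lyz2, a myeloid lysozyme gene, fell from 12.5 ± 3.58 to 3.98 ± 1.29 FPKM (-1.44 ± 0.28, adjusted p = 0.0075). Cd9 was higher only after scaling (0.34 ± 0.22, adjusted p = 0.33, 0.034 after scaling), and Plac8, Cd37, Adrb3 and Cela1 did not pass (adjusted p from 0.52 to 0.89).

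None of the lists kept as signs of RNA quality, nor the respiratory chain, passed as a list. Of the nuclear-encoded respiratory chain, 0 of the 43 tested members rose and 0 fell (camera adjusted p = 0.55, scaled 0.052), and Ndufa9, Ndufb5, Ndufs1 and Cox6c had the smallest p (adjusted p from 0.13 to 0.16). Scaled values gave 1 higher and 0 lower, against 0 and 0 adjusted over the list alone. Of mitochondrially encoded mRNAs, 0 of the 8 tested members rose and 0 fell (camera adjusted p = 0.55, scaled 0.13), with mt-Co3, mt-Atp6, mt-Nd4 and mt-Nd2 not passing (adjusted p from 0.45 to 0.58). The counts were 0 and 0 after scaling and 0 and 0 adjusted over the list alone. Of ribosomal proteins, 0 of the 44 tested members rose and 3 fell (camera adjusted p = 0.73, scaled 0.99). With scaling they numbered 0 and 2, and adjusted over the list alone 0 and 3. Rpl35 was listed at 0 in each dexamethasone library and at 1.39, 2.53, 2.65 and 1.33 FPKM in the vehicle libraries (adjusted p = 7.6e-04). Rpl27 fell (-0.94 ± 0.20, adjusted p = 0.013), Rpl5 was lower only as deposited (-0.77 ± 0.21, adjusted p = 0.040, 0.18 after scaling) and Rps4x did not pass (-0.82 ± 0.25, adjusted p = 0.058). Of replication-dependent histones, 0 of the 10 tested members rose and 0 fell (camera adjusted p = 0.23, scaled 0.29). Scaling gave 0 and 0, and 0 and 0 passed adjusted over the list alone. Of its members, Hist2h2ac, Hist1h2bc, Hist1h4d and Hist1h4b did not pass (adjusted p from 0.15 to 0.75).

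Camera called 6 lists higher and 2 lower of the 41 tested, and none of the 8 with an estimated correlation, by which 2 lists, glucocorticoid targets and gluconeogenesis, passed after median-ratio scaling (adjusted p = 0.0393 and 0.0495). The simulation started from values after median-ratio scaling, so recovery with the deposited values was not measured. In simulated values at this sample size, 44% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were called. A gene that did not pass is therefore not shown to be unchanged. The changed genes were drawn from those at about 2 FPKM or more with vehicle, so recovery of lower genes was not measured. The number of libraries, 4 in each group, limits the precision of each value.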

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

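Some tests were chosen only after the result was seen. They were those of Lars2 rescaling, of dexamethasone 4, of both Serpina3 explanations, and of scaling and CAR targets for Cyp2b10. The comparison of Cyp2b sequences and the splits taken list by list, both below, were not among the tests set beforehand either. More genes were lower than higher as deposited (85.1% of calls). Without dexamethasone 4 79.6% of calls were lower, which argues against that library as the whole cause. Median log2 fold changes over 5 equal bins of genes went from -0.42 at the lowest GC content to -0.15 at the highest (-0.16 to 0.12 after median-ratio scaling), and from -0.30 to -0.25 over bins of transcript length. Since the highest was -0.15, GC content or length as the whole cause is argued against, but a part for GC content is not. After rescaling each library to its fragments outside Lars2, 47.5% of calls were lower. Median-ratio scaling (50.9%) and quantile normalization (50%) balanced the calls too, so this does not single out Lars2. The larger Lars2 share may account for the imbalance, but the rescaling cannot decide it. A fall in mRNA of most genes with dexamethasone stays open and was not tested.

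Serpina3k and Serpina3m, which share 1 locus on chromosome 12 (104338486 to 104394257), were listed at 0 in dexamethasone 1, 2 and 3, and at 4080 and 138 FPKM in dexamethasone 4, far from the other dexamethasone libraries. All 12 values of both genes in those 3 libraries, in both kinds of column, were exactly 0, but these zeros are the pattern itself and do not test its cause. A failed estimate of the locus and a fall with dexamethasone cannot be told apart, since 1 dexamethasone library held Serpina3k above 0.

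Cyp2b10 rose, while of the 25 Cyp2 genes tested, itself included, 8 were lower as deposited and 6 of these also after scaling. Reads of Cyp2b9 or Cyp2b13 assigned to Cyp2b10 were examined as a source. Both were listed at 0 in each dexamethasone library (0% of Cyp2b10, which held 170 to 250 FPKM). The bound set beforehand, a share under 10%, could not exclude this alone, since reads gone to Cyp2b10 would also leave 0. But only 0.547% of 50-base windows of Cyp2b9 and 8.0% of Cyp2b13 occurred unchanged in Cyp2b10. Most of their reads would thus match their own gene better. Unless these zeros are failed estimates, they argue against such reads as the whole source. Windows with mismatches were not examined, so a part is not excluded. Scaling is argued against as the whole cause, since those 6 (Cyp2a5, Cyp2u1, Cyp2c37, Cyp2c50, Cyp2c54 and Cyp2c68) were lower and Cyp2b10 higher with it and without it. General activation of CAR targets was not decided. Of 20 other targets 3 were higher and 7 lower both as deposited and scaled. The median scaled log2 fold change of the 20 was -0.32 (95% interval -0.80 to 0.26). This interval treats genes as independent, so it does not measure the spread between mice. An effect of dexamethasone on each gene thus stays open.

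Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes (942, the highest other 1). After median-ratio scaling the real split gave 662 and the highest other 0. This argues against chance for these counts, at the smallest share that 35 splits can give (0.029). Each other split mixed both treatments, so the size of the gap adds no strength. For the number of lists called chance is not argued against, since 7 of the 35 splits gave as many (8, the highest other 13). List by list, 1 of the 35 splits, the real one, gave a camera p as small for glucocorticoid targets, cholesterol synthesis, interferon response, p53 targets and female-biased genes. That is the smallest share these splits can give (0.029), and 41 lists were examined, so it does not exclude chance for any 1 of them. For female-biased genes the real camera p was 0.0032 and the smallest of another split 0.0051. As many as 4 splits did for gluconeogenesis and for amino acid breakdown (1 each after scaling) and 6 for the acute phase (7 after scaling). Chance is thus not excluded for these 3 as deposited either.

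Of 396 groups of 4 values, 37 (9.34%) had a library far from the other 3, by a gap to the nearest that, over the range of the group, passed Dixon's 95% critical value. Chance passes it in about 1 in 20 groups of normally distributed values, and the rate for these values was not tested. Of the 37, 10 were in vehicle 1 and 10 in dexamethasone 4. In vehicle 1 these were FPKM of Cyp4a14 (58.5), Srebf1 (127), Cyp2a5 (198), Cyp2c54 (120), Oat (95.9), Col5a2 (0.794), Cd9 (9.18), Cyp2b9 (1.46) and Lars2 (13200), and the Lars2 share (14.5%). In dexamethasone 4 they were FPKM of Sort1 (0.343), Abcc2 (68.6), Ambp (246), Col14a1 (5.27), Col5a2 (0.206), Fkbp5 (46.8) and Hsd11b1 (85.6), the albumin share (2.6%), and the Serpina3 values above. In vehicle 2 Gldc was 6.66, Fgl1 60.5 and Clec9a 2.43 FPKM. In vehicle 3 Cdkn1a was 0.147, Igfbp2 224, Angptl4 42.7 and Il18 3.8 FPKM. In vehicle 4 Sc4mol was 31.3, Pex11a 5.9, Cyp2c40 18.4 and Pdgfra 0.736 FPKM. In dexamethasone 1 Saa1 was 452, Cxcl16 1.19, Fkbp4 10.8 and Cyp7a1 48.9 FPKM. In dexamethasone 2 Il18 was 0.393 and Cd163 4.46 FPKM.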

How the results depend on the processing

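The scaling between libraries set the balance of higher and lower genes, 140 and 802 as deposited. Quantile normalization gave 335 higher and 335 lower, median-ratio scaling 325 and 337, and, chosen after seeing the data, rescaling to fragments outside Lars2 gave 315 and 285, scaled fragment counts together with median-ratio scaling 538 and 540, median-ratio scaling without dexamethasone 4 gave 269 and 289, and with replicate number as a term 237 and 209. Without a filter 487 genes were lower, fewer than with it, and a minimum log2 fold change of 1, which removes genes by construction, left 97 higher and 422 lower. Leaving out each library gave 81 to 145 higher and 337 to 872 lower genes. Beyond 1.5 times, lower genes numbered 382, 337, 380 and 448 without vehicle 1, vehicle 2, vehicle 3 and dexamethasone 3, and higher genes 81 without dexamethasone 3. Other settings, among them pseudocounts of 0.1 and 0.5, robust fits, array weights and replicate number as a term, stayed within 1.5 times. Lists numbered 6 higher and 2 lower; camera with an estimated correlation called 0 and 0, fry 3 and 4, no filter 4 lower, and median-ratio scaling with an estimated correlation 2 and 0. Leaving out each library gave 4 to 8 higher and 2 to 4 lower lists, with 4 lower without dexamethasone 1. The difference in Lars2 share of 13.5 percentage points was 7.02 as a share of FPKM, chosen after seeing the data, and 8.25 to 15.8 with a library left out. With zeros of abundant genes as missing, Serpina3k (log2 fold change 0.60) and Serpina3m (1.63) changed sign, but this leaves 1 dexamethasone library, assumed to vary like the vehicle libraries, and says little. Except where the construction is stated, the cause was not tested. Over 187 genes and 4255 comparisons, 3875 kept the side of the threshold without a called direction turning (in 88 the sign differed with neither value passing), 292 lost the call, 86 gained it and 2, those of the Serpina3 genes, reversed; over 41 lists and 1064 comparisons these were 976, 42, 46 and 0. The DESeq2 alternative was not run because the values are not counts. Depth limits genes near 0.5 FPKM, where few fragments set the value.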

Other observations

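The gene families and sums here were examined after the data were seen, except for the sums of cell type markers. Families were formed by the stem of the gene symbol, and the 244 with at least 6 tested members were tested with camera. The carboxylesterases, enzymes that hydrolyse esters, were lower: of 13 tested Ces genes 7 fell and 0 rose, and the same 7, Ces1b, Ces1c, Ces1d, Ces1e, Ces1f, Ces1g and Ces2c, passed after median-ratio scaling (median log2 fold change -1.37, scaled -0.99, adjusted p = 0.0017, scaled 0.0046, adjusted p = 0.998 with an estimated correlation). Of 16 glucuronosyltransferase genes (Ugt) 9 fell and 0 rose as deposited, and Ugt2b35, Ugt2b38, Ugt1a8 and Ugt1a1 passed also after scaling (adjusted p = 0.044, scaled 0.0070, adjusted p = 0.998 with an estimated correlation). Of 13 hydroxysteroid dehydrogenase genes (Hsd) 5 fell as deposited, and Hsd3b2, Hsd3b3 and Hsd3b5 passed also after scaling, but the family passed only as deposited (adjusted p = 0.044, scaled 0.10, adjusted p = 0.998 with an estimated correlation).

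Summed FPKM of T cell markers was 4.01 ± 1.69 with vehicle and 1.14 ± 0.201 with dexamethasone (SD, n = 4, exact permutation p = 0.029, 0.12 adjusted over 13 sums), with no overlap between groups. Neutrophil markers summed to 1.62 ± 0.367 and 0.409 ± 0.194 (SD, n = 4, exact permutation p = 0.029, adjusted 0.12). The p of both was 0.029 after median-ratio scaling too, the smallest these groups can give, and no single marker of either list reached the filter. Dendritic cell markers summed to 44.3 ± 9.71 and 25.3 ± 8.03 (SD, n = 4, exact permutation p = 0.029, and 0.14 after scaling), and a single gene, Bst2, carried most of this difference (38.9 and 20.8 FPKM). Kupffer cell markers summed to 172 ± 17.8 and 172 ± 36.3 (SD, n = 4, exact permutation p = 1, and 0.057 after scaling), and endothelial markers to 138 ± 14.5 and 140.0 ± 28.1 (SD, n = 4, exact permutation p = 0.94, and 0.029, higher with dexamethasone, after scaling). Sums for B cells, NK cells, monocytes, stellate cells, cholangiocytes, red cells, adipocytes and acinar cells had exact permutation p from 0.11 to 0.69.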
